A study of Rattus norvegicus with 4 samples.

How the data were processed

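Total RNA of rat liver tissue was made into small RNA libraries with an Illumina small RNA kit, per the labels' protocols. The submitters' processing notes name CASAVA 1.4 and the rat genome build rn5. The aligner, the miRNA annotation version and the rule for reads that match several miRNAs are not given in the sources used here. Each of the 4 deposited files pairs 680 rat miRNA names, in the older style in which the minor arm carries an asterisk, with a value in reads per 1000000 reads (RPM) that the authors computed. The RPM are not counts, but each value is a whole multiple of what 1 read is worth (0.1439 RPM in fibrosis replicate 1, 0.1414 in normal replicate 1 and 0.1573 in the other 2 files). Dividing by that step gave whole reads for 100% of the values above 0, within 0.01 reads, and with them the totals the authors had scaled to. The reads on listed miRNAs were 50.5% to 52.5% of those totals, so the scaling total includes other reads. Members of families that differ by few bases, such as let-7, may exchange reads, and their separate values are uncertain for that reason.

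Groups were taken from the tissue label, 2 samples of hepatic fibrosis and 2 of normal liver. The files were compared before use. Fibrosis replicate 2 and normal replicate 2 agreed in all values, so the files used here lack an independent second replicate in at least 1 group, and the comparison planned before the data were examined was run as planned and its limits stated. That comparison assumed counts first and, for normalized values, limma 3.58.1 (R 4.3.3) on log2(RPM + 1) with a mean-variance trend and Benjamini-Hochberg adjustment, over miRNAs above 0 in at least 1 library. A fold change on the log2(RPM + 1) scale understates the change of low miRNAs. edgeR 4.0.16 and DESeq2 1.42.0 were run on the recovered reads as alternatives. Pearson's r and the ratios between libraries were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and the plots drawn with matplotlib 3.10.9.

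After the duplicate was found, fibrosis replicate 1 was compared with normal replicate 1 alone. The ratio of their RPM is given with a 95% interval from the exact (Clopper-Pearson) binomial interval of the reads of 1 library among the reads of both, which covers counting error only, since reads without molecular identifiers are not independent molecules. The miRNAs named from this pair are the 12 highest and the 12 lowest ratios among those with a mean of at least 10 RPM over the 2 libraries, a rule set after the duplicate was found and before the ratios were ranked. The rules set before the data were examined name the 10 most abundant miRNAs, the miRNAs past the threshold or, with fewer than 6, the 10 with the smallest p, and 11 miRNAs of prior interest with their values.

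A set of 18 lists with 148 distinct miRNAs was fixed before the data were examined, and 144 of these had a row. miR-148a-3p, miR-155-5p, miR-486 and let-7g-5p were not analysed here. Lists overlap: the list described as raised in fibrosis shares 4 members with the mesenchymal list and 2 with the miR-23/27/24 clusters, and the list described as lowered shares 3 with the hepatocyte list and 8 with the miR-29 and miR-30 families. Lists were tested on the 4-library fit with limma's camera at a preset correlation of 0.01 and with an estimated correlation, and with fry, adjusted over the lists. For the pair of libraries, the median log2 ratio of members with a mean of at least 1 RPM was placed among 10000 random lists. In these, each member was replaced by 1 of a window of 21 miRNAs around its abundance rank, the member itself included. For the most abundant members the window was the 21 most abundant miRNAs, so the match in abundance was loose there. Members of the same list can stand in the window, so the random lists draw partly on the list's own values. With 147 miRNAs in that pool the percentiles describe these libraries only.

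The limma fit was tested on simulated reads for the real miRNAs and totals, with 60 miRNAs changed 4-fold and a biological coefficient of variation of 0.1, in 20 simulations for each of 3 layouts. With 4 separate libraries 2.87% of the calls were false. Alternatives covered the scaling (TMM, DESeq2 size factors, reads on listed miRNAs, upper quartile, miR-122 left out), the pseudocount, filters on low values, the test, a stricter threshold, the replicate number as a block and leaving out each library. With 2 groups of 2 an exact permutation test cannot go below 0.333. No genome or miRNA coordinates were used.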

Results

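Small RNA libraries of rat liver were compared between tissue labelled as hepatic fibrosis and tissue labelled as normal, to ask which microRNAs (miRNAs, short RNAs that repress messenger RNAs) differ between the diseased and the healthy organ. The labels give 2 groups with 2 replicates each, and do not say whether the replicates came from separate animals. No p-value here can therefore be taken to measure the spread between animals. The 4 deposited files list the same 680 rat miRNA names. The files of fibrosis replicate 2 and normal replicate 2 hold identical values for each of the 680 names, with 0 differences. They were therefore counted as 1 library, called the duplicated library here, whose tissue is not settled by its labels. The column headers of 3 of the 4 files equal the sample titles, and that of normal replicate 2 does not. The data thus comprise 3 distinct libraries, of which fibrosis replicate 1 and normal replicate 1 each stand under 1 label.

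Depth was recovered from the size of the smallest steps in the values. The deposited values, reads per 1000000 reads (RPM), were scaled to 6951148 reads in fibrosis replicate 1, 7070374 in normal replicate 1 and 6357069 in the duplicated library, and 3507179, 3653412 and 3339603 of these reads fell on the listed miRNAs. At that depth 250 miRNAs had at least 1 read in fibrosis replicate 1, 239 in normal replicate 1 and 236 in the duplicated library. A count of 0 allows a level of up to 0.432 RPM, 0.424 RPM and 0.472 RPM in these libraries. These limits and the intervals below cover counting error only.

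The libraries were dominated by miR-122, the hepatocyte miRNA, and by the let-7 family, whose members target growth and cell cycle genes. miR-122 took 48.3% of the miRNA reads in fibrosis replicate 1 (95% exact binomial interval 48.3 to 48.4), 50.9% in normal replicate 1 (50.9 to 51.0) and 47.2% in the duplicated library (47.1 to 47.2). The let-7 names together took 47.6% (47.5 to 47.7), 44.7% (44.7 to 44.8) and 49.0% (48.9 to 49.04). The 10 most abundant miRNAs held 97.96% of the miRNA reads in fibrosis replicate 1, 97.95% in normal replicate 1 and 98.1% in the duplicated library. They were miR-122, let-7c, let-7f, let-7a, let-7b, miR-192, let-7d, let-7e, miR-29a and miR-101b. All 10 had counting intervals of the ratio of fibrosis replicate 1 to normal replicate 1 that excluded 1, but the ratios were small, from 0.834 (0.810 to 0.859) for miR-101b to 1.31 (1.30 to 1.32) for let-7b.

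No miRNA passed the comparison of fibrosis with normal liver that the labels imply. Over the 294 miRNAs seen in any library, limma on log2(RPM + 1) called 0 at an adjusted p under 0.05, and 4 had an unadjusted p under 0.05. The prior degrees of freedom of this fit were infinite. Each SE and p therefore came from the mean-variance trend over all miRNAs and not from the spread of that miRNA. The 10 smallest p-values belonged to miR-146b, miR-138, miR-27a, miR-106b*, miR-342-5p, miR-199a-3p, let-7b, miR-451, miR-144 and miR-503, each with an adjusted p of 1 from limma. Their fitted log2 differences, fibrosis over normal, were 0.88 for miR-146b (SE 0.36), 0.70 for miR-138 (SE 0.31), 0.89 for miR-27a (SE 0.40), 0.38 for miR-199a-3p (SE 0.24), 0.44 for miR-503 (SE 0.38), 0.46 for miR-342-5p (SE 0.27) and 0.20 for let-7b (SE 0.14). They were -0.39 for miR-106b* (SE 0.19), -0.55 for miR-451 (SE 0.43) and -0.40 for miR-144 (SE 0.33). Some rest on few reads in fibrosis replicate 1 against normal replicate 1: 14 against 1 for miR-138, 8 against 1 for miR-342-5p, 0 against 5 for miR-106b* and 5 against 14 for miR-144. Leaving out 1 library at a time moved the fitted differences widely, that of miR-146b from 0.0099 to 1.76, and turned the direction of 4 of the 10. The 0.0099 and the turned directions came from leaving out normal replicate 1. The duplicated library then stands in both groups without a separate normal library, so they are not evidence on the tissues. On the reads recovered from the RPM, edgeR's quasi-likelihood test, edgeR's exact test, limma-voom and DESeq2 each called 0. At an unadjusted p under 0.05 there was 1 miRNA in the quasi-likelihood test without a filter (294 miRNAs), and 0 in that test after filtering (142 miRNAs) and in each of the others.

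This comparison had almost no ability to call a miRNA, because 1 library sat in both groups. Each fitted difference is then the mean of the difference between the other 2 libraries and 0, and a t statistic without moderation cannot exceed 1.41 in size, which corresponds to a two-sided p of 0.293. With limma's moderation the largest t reached 2.48 in size. In simulated data with 60 miRNAs changed 4-fold, the same test recovered 95.8% of them from 4 separate libraries and 0% with 1 library in both groups. The simulated biological coefficient of variation, 0.1, was set and not estimated from these libraries. Smaller changes and a wider spread were not simulated. Counting the duplicated library once gave 0 calls as well: limma called 0 with it in the fibrosis group, with 36 miRNAs at an unadjusted p under 0.05 and a smallest adjusted p of 0.295, and 0 with it in the normal group, with 27 and 0.248. In these fits the lone library is assumed to vary like the other group. The layout of 2 fibrosis libraries against 1 normal library recovered 20.7% of the simulated 4-fold changes, and the reverse layout was not simulated. The changed miRNAs in all simulations had a mean of at least 1 RPM.

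Between fibrosis replicate 1 and normal replicate 1, miR-146b, which represses inflammatory signalling, showed the highest ratio among the 76 miRNAs with a mean of at least 10 RPM. It stood at 33.7 RPM in fibrosis replicate 1 and 9.19 RPM in normal replicate 1, a ratio of 3.66 (95% counting interval 2.77 to 4.90), and at 33.2 RPM in the duplicated library. Ratios above 1.5 were also seen for miR-503, a cell cycle regulator, at 1.92 (1.41 to 2.65), for miR-33, which lies within an Srebf gene and represses cholesterol export, at 1.78 (1.27 to 2.52), for miR-199a-3p, made by mesenchymal cells including stellate cells, at 1.69 (1.61 to 1.78), and for miR-532-5p at 1.51 (1.27 to 1.80). In the deposited RPM the only miRNA lower by as much was miR-143, a smooth muscle and fibroblast miRNA, at 62.1 RPM against 97.3 RPM, a ratio of 0.639 (0.565 to 0.721), which fell short of 1.5-fold with TMM scaling. miR-532-5p fell short of 1.5-fold with upper-quartile factors and with miR-122 left out. The division into 5 higher and 1 lower depended on the scaling: it was 8 and 0 with TMM, 8 and 1 with library size only, 6 and 1 with DESeq2 size factors, 4 and 2 with miR-122 left out, and 4 and 3 with upper-quartile factors. With 1 library on each side this difference has no replicate check, so these values describe the 2 libraries and not the conditions.

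The next highest ratios belonged to miR-142-5p, a blood cell miRNA (1.49, 1.23 to 1.80), miR-181a (1.47, 1.22 to 1.79), miR-181b (1.47, 1.08 to 2.01), miR-27b (1.37, 1.06 to 1.78), miR-139-3p (1.36, 1.01 to 1.85), miR-24 (1.33, 1.10 to 1.61) and miR-872 (1.32, 1.05 to 1.67). The next lowest were miR-145, transcribed together with miR-143 (0.671, 0.482 to 0.930), miR-194 (0.692, 0.602 to 0.795), miR-193 (0.712, 0.573 to 0.881), miR-92a (0.712, 0.581 to 0.871), miR-365* (0.725, 0.515 to 1.02), miR-499 (0.760, 0.595 to 0.967), miR-16 (0.765, 0.670 to 0.873), miR-101a (0.769, 0.711 to 0.831), miR-30c-2* (0.789, 0.577 to 1.08), miR-29c (0.790, 0.719 to 0.867) and miR-22 (0.798, 0.717 to 0.888). The intervals of miR-365* and miR-30c-2* included 1. Of the 76 miRNAs, 44 had intervals that excluded 1, with 18 higher and 26 lower in fibrosis replicate 1, and the median ratio was 0.926.

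**Figure D1:**
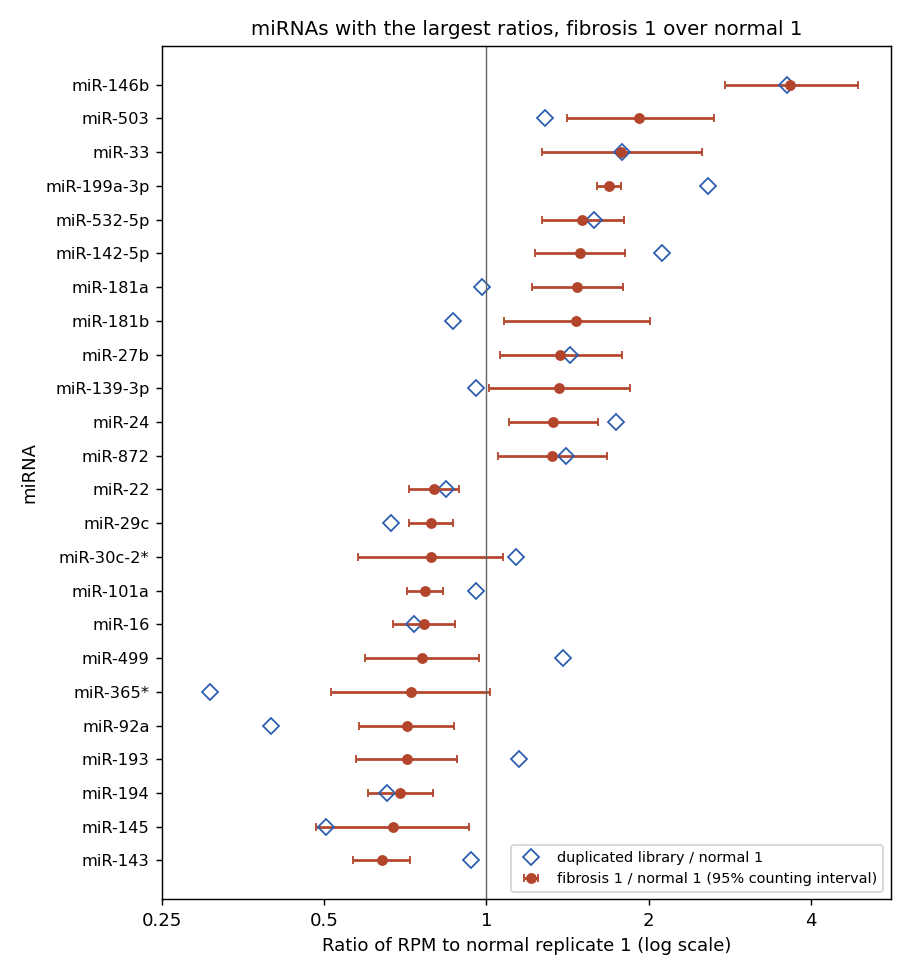
Ratio of RPM to normal replicate 1 on a log scale for the 12 miRNAs with the highest and the 12 with the lowest ratio of fibrosis replicate 1 to normal replicate 1, among those with a mean of at least 10 RPM. Filled circles give fibrosis replicate 1 with 95% counting intervals and open diamonds the duplicated library, which coincides with fibrosis replicate 1 for miR-146b and miR-33 and lies at 0.982 times normal replicate 1 for miR-181a.

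The duplicated library did not side with either of the other libraries throughout. Among the 12 miRNAs with the highest ratios it was nearer to fibrosis replicate 1 for 8 and nearer to normal replicate 1 for 4, and among the 12 with the lowest for 7 and 5. It exceeded both other libraries for miR-199a-3p, at 903.4 RPM against 592.0 and 350.5 RPM, and for miR-142-5p, at 56.0 RPM against 39.4 and 26.4 RPM. It lay below both for miR-92a, at 13.5 RPM against 24.2 and 33.9 RPM. If 1 of its 2 labels is right, the duplicated library forms a replicate pair with 1 of the others. Both possible pairs differed by 1.5-fold in more miRNAs than fibrosis replicate 1 and normal replicate 1 did. At a mean of at least 10 RPM, 14 of 72 miRNAs differed at least 1.5-fold between it and fibrosis replicate 1, 20 of 73 between it and normal replicate 1, and 6 of 76 between fibrosis replicate 1 and normal replicate 1. At least 2-fold differences numbered 1, 5 and 1 in these pairs. The median absolute log2 ratio was 0.28, 0.33 and 0.24, and Pearson's r of log2(RPM + 1) across miRNAs, which are not independent replicates, was 0.992, 0.989 and 0.994, with Spearman's rho of 0.923, 0.912 and 0.930. The chi-square of the reads over all detected miRNAs ordered the pairs otherwise and was largest between fibrosis replicate 1 and normal replicate 1, at 11378, 22127 and 26236 in the same order (273, 271 and 276 degrees of freedom). The 10 most abundant miRNAs contributed 68.6%, 74.8% and 94.3% of it.

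Hepatocyte miRNAs lay lower in fibrosis replicate 1 for each of the 9 members measured, with log2 ratios from -0.53 to -0.068 and without a test of the conditions. miR-122 stood at 243915 RPM against 263140 RPM (ratio 0.927, 0.925 to 0.929), miR-192 at 7826 RPM against 8936 RPM (0.876, 0.866 to 0.886) and miR-194 at 49.9 RPM against 72.1 RPM. The duplicated library lay above both others for miR-193, between them for miR-122, miR-101a and miR-101b, and below both for miR-192 and miR-194. The list median was a log2 ratio of -0.26, at percentile 2.46 of the 10000 random lists, and 7 of the 9 intervals excluded 1. The random lists drew partly on the members themselves and matched miR-122 only loosely in abundance. In the 4-library fit 0 members passed, over all miRNAs or adjusted over the list alone, and camera gave the list an adjusted p of 0.066 with the preset correlation and an adjusted p = 0.75 with an estimated correlation. With 1 library in both groups, camera on that fit rests on the same difference between fibrosis replicate 1 and normal replicate 1 as the percentile. It is no separate check on the tissues, here or for the lists below. With a pseudocount of 10 camera's adjusted p was 0.00396, and an adjusted p = 0.74 with an estimated correlation. The erythroid miRNAs also lay lower in fibrosis replicate 1, with miR-451 at 2.16 RPM against 5.80 RPM (0.372, 0.191 to 0.687) and miR-144 at 0.719 RPM against 1.98 RPM (0.363, 0.102 to 1.07). In the duplicated library miR-451 stood at 1.73 RPM and miR-144 at 0.315 RPM.

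The miRNAs described as raised in activated stellate cells, the collagen-producing cells of the fibrotic liver, lay on both sides. Of the 13 measured, 8 were higher and 5 lower in fibrosis replicate 1, with 6 and 3 intervals that excluded 1, and the median log2 ratio of 0.38 stood at percentile 99.9 of the random lists. miR-199a-3p, miR-33, miR-181a, miR-181b, miR-27b and miR-27a were the 6 with intervals above 1, miR-27a at 6.76 RPM against 1.27 RPM (5.31, 2.57 to 12.3). miR-21, a miRNA widely linked to fibrosis, was at 934 RPM in fibrosis replicate 1, 1042 RPM in normal replicate 1 (0.897, 0.867 to 0.927) and 1178 RPM in the duplicated library. miR-199a-5p (0.838, 0.382 to 1.81), miR-214 (1.30, 0.671 to 2.56) and miR-34a (2.03, 0.292 to 22.5) had intervals that included 1, on 14, 23 and 4 reads in fibrosis replicate 1. In the 4-library fit 0 members passed, over all miRNAs or adjusted over the list alone, and camera gave an adjusted p of 0.066, and an adjusted p = 0.75 with an estimated correlation. With TMM scaling camera's adjusted p was 0.047, and an adjusted p = 0.84 with an estimated correlation.

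The miRNAs described as lowered in fibrotic liver gave 12 lower and 2 higher members of 14 measured, 6 of the lower with intervals that excluded 1. The miR-29 family, which represses collagen genes, was lower for all 3 members in fibrosis replicate 1, with miR-29a at 1543 RPM against 1752 RPM (0.881, 0.858 to 0.904), miR-29b at 12.7 RPM against 14.6 RPM (0.869, 0.646 to 1.17) and miR-29c at 115 RPM against 146 RPM. The duplicated library held 1635 RPM, 8.49 RPM and 97.1 RPM of these. Of the miR-30 family 4 members were lower and 1 higher, with only the interval of miR-30b-5p excluding 1 (12 reads against 28). The list medians, -0.20, -0.20 and -0.17 on the log2 scale for the lowered list, the miR-29 family and the miR-30 family, stood at percentiles 23.6, 19.6 and 54.3. By camera on the 4-library fit their adjusted p-values were 0.089, 0.44 and 0.29 (each adjusted p = 0.75 with an estimated correlation), with 0 members passing over all miRNAs or adjusted over the list alone. With the duplicated library counted once, the adjusted p of the lowered list was 0.023 if it was counted as fibrosis and 0.77 if as normal, and an adjusted p = 0.76 and 0.97 with an estimated correlation.

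The let-7 family divided into members on each side of 1. let-7b, let-7c (1.18, 1.18 to 1.19), let-7e (1.17, 1.13 to 1.20) and let-7i (341 RPM against 291 RPM) were higher in fibrosis replicate 1, and let-7a (0.921, 0.917 to 0.925), let-7d (0.928, 0.913 to 0.944), let-7f (0.894, 0.890 to 0.897) and miR-98 (9.35 RPM against 10.5 RPM, a ratio of 0.893, 0.630 to 1.26) lower, the last with an interval that included 1. The median log2 ratio of the 8 was 0.06, at percentile 95.3. The abundant let-7 members were themselves among the miRNAs from which these random lists were drawn. The miR-23/27/24 clusters had 4 of 5 members higher, with a median of 0.41 at percentile 93.0, and the miR-17/92 and related clusters had 6 of 7 members lower, with a median of -0.49 at percentile 4.56 and only the interval of miR-92a excluding 1. By camera their adjusted p-values were 0.64, 0.16 and 0.72 for the let-7, miR-23/27/24 and miR-17/92 lists, and 0.81, 0.75 and 0.90 as adjusted p-values with an estimated correlation. In the 4-library fit 0 members of these 3 lists passed, over all miRNAs or adjusted over the list alone.

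Markers of other cell types lay on no common side. The leukocyte list had 4 measured members, 2 higher (miR-146b and miR-142-5p) and 2 lower (miR-342-3p and miR-146a). The intervals of both higher members and of 1 lower member excluded 1. The list median of 0.12 stood at percentile 81.5. Below the minimum for lists, miR-223 and miR-150 stood at 1.01 RPM each in fibrosis replicate 1 against 0.283 and 0.566 RPM. Their intervals included 1 (7 against 2 reads and 7 against 4 reads). The mesenchymal and smooth muscle list had 3 higher and 7 lower of 10 measured, with a median of -0.25 at percentile 15.7. Both endothelial miRNAs, miR-126 and miR-126*, had intervals that included 1, on 12 and 42 reads in fibrosis replicate 1. Of the biliary and other epithelial list, 5 of 6 were lower with a median of -0.17 at percentile 50.2, and of the miR-15/16 family 4 of 5 were lower with a median of -0.21 at percentile 36.2. The striated muscle miRNAs miR-1 and miR-499 were both lower, with a median of -0.76 at percentile 0.955. The duplicated library exceeded both fibrosis replicate 1 and normal replicate 1 for each of them. It held miR-499 at 31.8 RPM against 17.4 and 22.9 RPM, and miR-1 at 5.82 RPM against 2.01 and 4.38 RPM. The neural, pancreatic and pituitary list had a median of 0.08 over 3 members at percentile 68.6, the miR-34 family had 1 member above 1 RPM, and the imprinted Dlk1-Dio3 cluster had 0. In the 4-library fit 0 members of these lists passed, over all miRNAs or adjusted over the list alone. Camera's adjusted p-values were 0.64 for the leukocyte, 0.33 for the mesenchymal, 0.066 for the erythroid and striated muscle, 0.54 for the endothelial, 0.65 for the epithelial and Dlk1-Dio3, 0.64 for the miR-15/16 and miR-34, and 0.96 for the neural list, and none passed with an estimated correlation. With TMM scaling the erythroid and striated muscle lists had an adjusted p of 0.047 each, and an adjusted p = 0.84 with an estimated correlation.

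**Figure D2:**
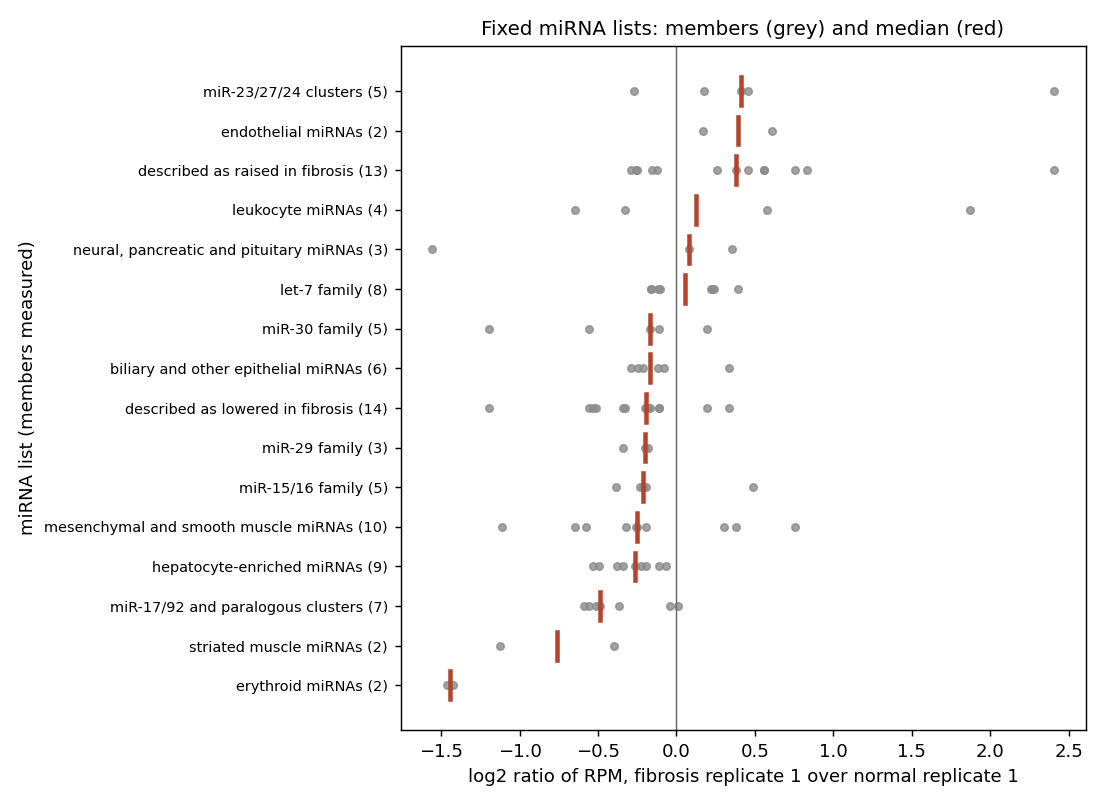
Log2 ratio of RPM in fibrosis replicate 1 over normal replicate 1 for the members of each miRNA list with a mean of at least 1 RPM (grey points, number measured in brackets) and the list median (red bar). All 9 hepatocyte members lie below 0, and the list described as raised in fibrosis has 8 of 13 members above 0.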

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

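The count of miRNAs past the threshold in the 4-library comparison was 0 under each of 20 alternatives, including a replicate block (0 calls, smallest adjusted p from limma 0.602) and each library left out (0 to 0), so no call could be lost, and the layout with 1 library in both groups limits what these alternatives can show. The labels do not say that equal replicate numbers mark a pair, and the correlation of same-numbered deviations, 0.68, is forced upward by the shared library, so the block is reported here only. TMM scaling, the log2 CPM of the recovered reads and the mean of at least 1 RPM were chosen after seeing the data. So was the filter in edgeR's quasi-likelihood test (142 miRNAs). The quasi-likelihood test without a filter (294 miRNAs) was set before the data were examined. For lists, 22 of 275 list tests in other settings passed with camera's preset correlation and 0 with an estimated correlation (smallest adjusted p = 0.72), and fry called 0. The values that follow are list medians of the log2 difference. With a call gained, the hepatocyte list gave -0.10 with pseudocount 10 and -0.10 with the replicate block. The list described as raised in fibrosis gave 0.21 with TMM, 0.19 with DESeq2 size factors and 0.16 with upper-quartile factors. The erythroid list gave -0.48, -0.50 and -0.52 and the striated muscle list -0.20, -0.21 and -0.23 in these 3 scalings, and the miR-23/27/24 list gave 0.17 with upper-quartile factors. The direction of camera's test turned, with no call, for the miR-17/92 list without miR-122 (-0.12), with pseudocount 0.1 (-0.10) and in the log2 CPM without a filter (-0.069), for the miR-34 list with the replicate block (-0.036), and for the neural, pancreatic and pituitary list with TMM (0.016), DESeq2 size factors (0.0060), at least 1 RPM in at least 2 libraries (0.039) and the log2 CPM after filtering (0.10), and in each of these the median and the test differed in sign. Leaving out 1 library at a time gained a call or turned the direction of camera's test for most lists, with these ranges of the median: -0.015 to 0.14 for the raised list, -0.34 to 0.079 for the lowered list, -0.45 to 0.12 for miR-29, -0.40 to 0.21 for miR-30, -0.14 to 0.054 for the mesenchymal, -0.093 to 0.25 for the leukocyte, -0.99 to 0.13 for the erythroid, -0.20 to 0.45 for the endothelial, -0.11 to -0.028 for the epithelial, -0.10 to 0.16 for let-7, -0.36 to 0.18 for miR-17/92, -0.11 to 0.041 for miR-34, -0.027 to 0.46 for miR-23/27/24, -0.19 to -0.10 for Dlk1-Dio3, -0.42 to 0.029 for striated muscle and -0.011 to 0.064 for the neural list. For the epithelial and Dlk1-Dio3 lists camera's direction turned while the median stayed below 0. For the 2 other lists no call was gained and camera's direction did not turn, but the median crossed 0, from -0.21 to 0.0099 for the hepatocyte and -0.16 to 0.063 for the miR-15/16 list. The calls gained with fibrosis replicate 1 left out (7 lists) and with normal replicate 1 left out (2 lists) compare a library with a group that contains it, and are not evidence on the tissues. The same limit holds for the list medians of these fits in the ranges above and for their single-miRNA values below. Of single miRNAs, the 10 with the smallest p-values were followed. Leaving out normal replicate 1 turned the log2 difference of 4 of them, with ranges over the 4 fits of -0.99 to 0.19 for miR-144, -1.21 to 0.10 for miR-451, -0.30 to 1.06 for miR-199a-3p and -0.34 to 2.11 for miR-27a. The other 6 kept their direction but moved widely: 0.0099 to 1.76 for miR-146b, 0.18 to 1.22 for miR-138, 0.10 to 0.81 for miR-342-5p, 0.17 to 0.71 for miR-503, 0.041 to 0.35 for let-7b and -0.77 to -0.39 for miR-106b*. Between fibrosis replicate 1 and normal replicate 1, the number of miRNAs that differed 1.5-fold stayed within 1.5 times under every scaling, but its division, 5 higher and 1 lower in the deposited RPM, ran from 8 and 0 with TMM to 4 and 3 with upper-quartile factors. The number rose to 28 of 147 at a mean of at least 1 RPM (12 higher, 16 lower), where fewer reads limit the precision. The 10 most abundant miRNAs held 96.5% of the reads with miR-122 left out. Lists with fewer than 2 members left under a stricter filter gave no value. The cause of these shifts was not tested.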

Other observations

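The tests of the repeated values and of the 6 miRNAs, apart from the simulated resequencing and the scaling tests, were chosen only after the result was seen. Beyond the comparison, 4 of the 205 miRNA names listed with both arms had the arm marked as minor above its partner in all 3 distinct libraries at a mean of at least 10 RPM. miR-423* stood at 1075 RPM in fibrosis replicate 1, 1237 RPM in normal replicate 1 and 630 RPM in the duplicated library, against 1.87, 1.84 and 1.42 RPM for miR-423. miR-140* stood at 880, 868 and 860.1 RPM, with 0.144 RPM of miR-140 in fibrosis replicate 1 and 0 reads in the other 2 libraries. miR-322* exceeded miR-322 by 12.2, 13.9 and 15.3 times, and miR-511* stood at 12.1, 13.2 and 23.0 RPM with at most 0.141 RPM of miR-511.

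The first pattern is the pair of files with identical values. Of the 236 miRNAs detected, 0 differed in reads between fibrosis replicate 2 and normal replicate 2. In 1000 simulated pairs of libraries with the same mean reads and counting error only, at least 191 miRNAs differed, which argues against 2 libraries sequenced separately, and 1 library deposited under both labels is a candidate explanation that accounts for the values. Which label is right stays open: 3 of the 4 column headers equal their sample titles and that of normal replicate 2 does not, but no source used here ties that header to a tissue.

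The second pattern is the 6 miRNAs that differed at least 1.5-fold between fibrosis replicate 1 and normal replicate 1 (miR-146b, miR-503, miR-33, miR-199a-3p and miR-532-5p higher, miR-143 lower). Counting error is argued against as the cause of all 6: in 1000 simulated pairs, with the reads of each of the 76 miRNAs divided at the median ratio and counting error only, at most 3 reached 1.5-fold. At least 5 of the 6 kept their direction and size under each of the 5 other scalings, but this decides nothing about the scaling. A scaling moves all miRNAs alike, and these moved the log2 ratios by at most 0.071, which could bring at most 1 of the 6 below 1.5-fold under any single scaling. That was miR-143 with TMM, and miR-532-5p with upper-quartile factors and with miR-122 left out. Variation between libraries of 1 group cannot be told apart from a difference between fibrotic and normal tissue, since the duplicated library differed at least 1.5-fold from fibrosis replicate 1 for 1 of the 6 and from normal replicate 1 for 4 of the 6, and its group is not settled. Each of the 6 differed by less than the simulated 4-fold, so the simulated share below does not hold for changes of their size. That share was simulated only for 2 fibrosis libraries against 1 normal library. The fits that counted this library once called 0 miRNAs, in a layout that recovered 20.7% of simulated 4-fold changes.

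The third pattern is the division of the let-7 list, with 4 members above and 4 below 1, of which miR-98 had a counting interval that included 1. At least 4 members stayed on each side under each of the 5 other scalings, but this decides nothing about the scaling here either, since the shift of at most 0.071 was less than the 0.11 of the member nearest to 1. The 7 let-7 members summed gave a ratio of 1.04 (95% counting interval 1.036 to 1.041), but 0.988 with upper-quartile factors, so its direction depended on the scaling. An exchange of reads between near-identical members, a difference in library preparation and a difference between the tissues were not tested and stay open.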
